A study of Mus musculus with 9 samples.

How the data were processed

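RNA was taken from primary CD4+ T cells of C57BL/6 mice after retroviral transduction, extracted with a column kit and sequenced as paired ends, per the labels' protocols. There were 9 libraries in 3 groups of 3: Control, NFAT2-CA and NFAT2-CARIT. The deposited expression values are in CPM, reads per gene scaled to a fixed library total: each library's values for the 16500 listed genes sum to the same total, and the authors added 0.0001 to every value, both checked on the file. The deposited comparison table, made by the authors with DESeq2 in Partek 10 per the submitters' processing notes, gives for each comparison a p-value, a step-up FDR, a ratio of group means and the log2 of that ratio, per the file headers. Its deposited column of total counts equals the sum of the 9 CPM values (largest relative difference 3.2e-06). Whether their test took CPM values or reads is not stated. The build is mm10 per the submitters' processing notes. The aligner, the quantifier, the annotation and the use of strand are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be assigned with certainty. Of the listed genes, 15961 (96.7%) share strand and span with GENCODE M21 on GRCm38, and coordinates are given as the authors' files list them. No gene of the mitochondrial chromosome is listed.

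Low values in each library lie mostly on multiples of 1 step, which gave the read depth of each library (19947800 to 38189000 reads). With these depths, 81.2% to 84.3% of values up to 1 CPM were whole numbers of reads within 0.1 read, fewer than the 95% set for treating them as reads, so read counts were not rebuilt. In the Control libraries 3 reads equal 0.095 to 0.128 CPM, which covers counting error only. Replicates differed beyond sampling noise (median chi-square per gene 1.29 to 3.18), so none is a copy of another.

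Tests were run with limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with a mean per group over all 9 libraries, empirical Bayes with trend and robust settings, and Benjamini-Hochberg adjustment. A gene was tested if it reached 10 CPM in at least 3 libraries, which left 9233 genes, and called at an adjusted p under 0.05. The filter had been set at a value of 10 before the unit was known. In CPM it is stricter than intended, and it was kept. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used to read the files and draw the figures. The test was tried on simulated data for NFAT2-CA against Control with 8904 genes tested. It recovered 39 of 50 genes (78%) changed by 0.3 on the log2 scale, 50 of 50 at 0.6, 50 of 50 at 1 and 49 of 50 (98%) at 2, with 10 false calls among 8704 unchanged genes.

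The comparisons were NFAT2-CA and NFAT2-CARIT against Control and NFAT2-CARIT against NFAT2-CA. Genes changed by both vectors were counted per direction and set beside the number from independent lists (the product of both counts over the genes tested) and beside 50 simulations of unchanged groups against the same controls. A gene counted as weaker, opposite or stronger with NFAT2-CARIT only where the difference between the vectors itself was called. Gene lists were tested with limma's camera at an inter-gene correlation of 0.01, with an estimated correlation and limma's fry beside it, adjusted over the 20 lists with at least 3 tested members. The lists were effector cytokines, chemokines, coinhibitory and exhaustion, anergy, naive and memory, regulatory T cell, follicular helper, Th1 and cytotoxic, Th2, Th17, NFAT and calcineurin, AP-1, IRF and related factors, cell cycle, glycolysis, sterol synthesis, amino acid stress response, apoptosis, interferon-stimulated, T cell receptor signalling, adhesion and migration, and markers of CD8 T cells, B cells, myeloid and dendritic cells, NK cells, erythroid cells and platelets, the mitochondrial chromosome and histones. Some genes sit in several lists, such as Il10, Il21, Ccr8, Cd200 and Fasl.

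The lists, the tests, the thresholds and the rule for naming genes were fixed before the data were examined. Named were Nfatc1 and, in each comparison, the 6 largest rises and 6 largest falls among called genes with a mean of at least 50 CPM in the higher group and no overlap between libraries, leaving out gene models, olfactory receptors and antigen receptor segments. Up to 4 called members with the largest change were named for each list described. Il2, Ifng, Tnf, Il4, Csf2, Pdcd1, Havcr2, Lag3, Tigit, Ctla4, Tox, Tcf7, Foxp3, Egr2 and Rcan1 were read out whatever their result. Thy1, Actb, the chaperone genes other than Hspa1a and Hspa1b, and the marker and library genes Ighm, Cd79b, Cd8b1, Itgam, H2-Eb1, H1f0, Ccl5, Malat1 and Neat1 were picked out after their values were seen. Some genes that the rule names are not reported here.

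The alternatives were pseudocounts of 0.5 and 5, no filter, a filter of 50 CPM, TMM factors, quantile normalization, only the 6 libraries compared, the replicate number as a block, array quality weights, each library left out in turn, an estimated correlation for the lists, and the authors' deposited table. A filter of 1 CPM was added after the data were seen.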

Results

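Paired-end RNA sequencing was carried out on primary mouse CD4+ T cells from C57BL/6 animals that carried 1 of 3 retroviral vectors: a control vector, NFAT2-CA or NFAT2-CARIT. NFAT2 is the transcription factor encoded by Nfatc1, which calcium signalling normally activates through calcineurin. The CA form is active without that signal, and the RIT changes impair its cooperation with the partner factor AP-1 (Fos and Jun proteins) on DNA. Each group had 3 libraries, 9 in all. The labels do not say whether the libraries came from separate animals or cultures, so the p-values measure only the spread between these libraries. The deposited values are in CPM, the reads of a gene scaled to a fixed library total, for 16500 genes, of which 9233 were tested. Read depth, estimated from the spacing of the lowest values, was 23518200, 31738200 and 23996200 reads in Control replicates 1, 2 and 3. It was 26885400, 23861600 and 23714200 reads with NFAT2-CA and 38189000, 36414600 and 19947800 reads with NFAT2-CARIT. A value of 10 CPM then rests on 199 to 382 reads. Values are given as mean ± SD (n = 3 libraries per group), and log2 fold changes, on CPM + 1, as estimate ± SE with the adjusted p from limma.

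Nfatc1, the gene whose product the vectors carry (chromosome 18, 80606205 to 80713071, GRCm38), was measured first in each library. In Control it stood at 224, 228 and 188 CPM. It was 342, 336 and 395 CPM with NFAT2-CA and 240.5, 245 and 253 CPM with NFAT2-CARIT. The rise with NFAT2-CA was 0.74 ± 0.08 on the log2 scale (adjusted p = 2.6e-07), from 214 ± 22.1 to 358 ± 32.7 CPM. NFAT2-CARIT libraries held 246 ± 6.48 CPM, a log2 fold change of 0.21 ± 0.08 against Control (adjusted p = 0.021). That second call rests on single libraries: it was 0.12 (adjusted p = 0.094) without Control replicate 3 and 0.19 (adjusted p = 0.064) without NFAT2-CARIT replicate 3. The authors' deposited table gives the same comparison as 0.21 (adjusted p = 0.19). Nfatc1 was lower with NFAT2-CARIT than with NFAT2-CA by a log2 fold change of -0.53 ± 0.08 (adjusted p = 7.2e-05). The files do not say whether reads from the vector insert count towards Nfatc1, so these values cannot be read as the amount of vector.

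Both NFAT2 vectors changed most of the genes tested with limma, and fewer in the authors' deposited table. The first principal component held 86.4% of the variance and separated the 3 Control libraries (scores -52.6 to -51.8) from the 6 NFAT2 libraries (21.8 to 30.8). The second held 8.8% and separated NFAT2-CA (-15.2 to -14.6) from NFAT2-CARIT (13.5 to 14.2).

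The first comparison asks what constitutively active NFAT2 does to the transcripts of these cells. NFAT2-CA raised the coinhibitory receptor gene Lag3 17.8-fold, from 60.8 ± 5.18 to 1085 ± 36.8 CPM (n = 3 per group). It raised Nr4a2, which encodes a nuclear receptor linked to T cell dysfunction, from 4.32 ± 0.0831 to 219 ± 8.03 CPM. Genes of sterol synthesis and cell division rose as groups, with Cyp51, the lanosterol demethylase gene, going from 41.2 ± 1.34 to 385 ± 21.8 CPM. Igfbp4, a growth factor binding gene of the naive and memory list, fell from 184.5 ± 7.64 to 53.9 ± 3.71 CPM.

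In numbers, 6650 of 9233 genes (72.0%) differed between NFAT2-CA and Control, 2914 up and 3736 down. The excess of falls depends on the scaling, with 3253 up and 3322 down under TMM factors. The authors' deposited table calls 3602 of 16500 genes, 1884 up and 1718 down, and keeps 3228 of the 6650 limma calls. Of these 6650 genes, 1230 changed at least 2-fold, 732 up and 498 down. The median size of a called change was 0.50 on the log2 scale, against a median SE of 0.076. The libraries of the groups did not overlap for 6742 genes (73.0%), against 10% by chance for 3 libraries against 3.

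The largest rises with NFAT2-CA among genes of at least 50 CPM were in genes nearly silent in Control. Hspa1a, which encodes an inducible HSP70 chaperone, rose by 6.20 ± 0.15 on the log2 scale (adjusted p = 2.6e-12), from 0.51 ± 0.404 to 108 ± 10.2 CPM. Its near-identical neighbour Hspa1b rose from 1.00 ± 0.568 to 114 ± 5.91 CPM, and reads shared between the pair leave the division between them uncertain. Nos2, the inducible nitric oxide synthase, rose by 6.20 ± 0.08 (adjusted p = 1.7e-18), from 0.116 ± 0.0447 to 80.9 ± 4.69 CPM. Plek, a protein kinase C substrate of blood cells, rose by 6.19 ± 0.06 (adjusted p = 2.8e-19), from 1.97 ± 0.125 to 216 ± 8.42 CPM. Gja1, the gap junction gene on chromosome 10 (56377330 to 56402513), rose by 6.07 ± 0.14 (adjusted p = 1.8e-15), from 0.399 ± 0.0527 to 93.3 ± 8.20 CPM. Hdc, the histamine-forming enzyme, rose from 0.908 ± 0.116 to 84.3 ± 6.82 CPM. With Control values this low, the size of these log2 fold changes depends on the added 1 CPM.

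Among the falls, Ms4a4b, a membrane protein gene of resting T cells with close relatives in its cluster, fell by 4.55 ± 0.16 on the log2 scale (adjusted p = 7.7e-10), from 325 ± 43.0 to 13.2 ± 3.51 CPM. Cd226, a costimulatory receptor that competes with TIGIT for ligands, went from 92.6 ± 7.32 to 5.55 ± 0.127 CPM (adjusted p = 1.7e-14). Sytl2, a vesicle trafficking gene, went from 56.5 ± 1.96 to 3.60 ± 0.496 CPM. The interferon-inducible genes Ifi206 and Ifi203 had log2 fold changes of -3.73 ± 0.14 and -3.57 ± 0.16, and the GTPase gene Tgtp1 had -3.29 ± 0.09. Ifi206, Ifi203 and Tgtp1 belong to families of near-identical copies, so their separate values are uncertain.

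**Figure D1:**
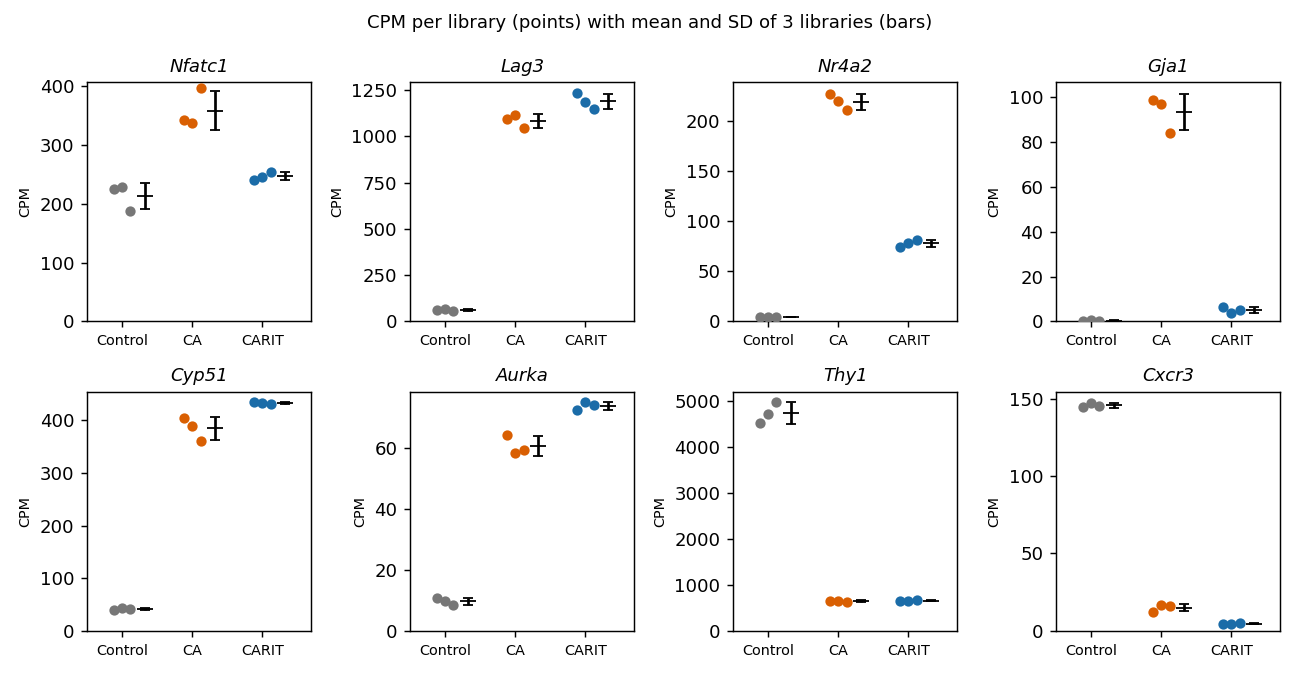
CPM in each library (points) for 8 genes in the Control, NFAT2-CA and NFAT2-CARIT groups, with the mean and SD of 3 libraries as bars and linear axes from 0. Thy1 was chosen after its values were seen. Lag3 stands at 1085 and 1189 CPM with the NFAT2 vectors against 60.8 CPM in Control, while Gja1 is at 93.3 CPM with NFAT2-CA and 4.94 CPM with NFAT2-CARIT.

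Of 20 gene lists with enough tested members, 11 differed from the other genes in the comparison of NFAT2-CA with Control. Of these, 8 moved towards higher and 3 towards lower expression. Splits that mixed these libraries across the groups still set 3 to 7 lists apart, with 0 genes called. Such splits keep part of the group difference, so these counts do not measure chance. All 23 tested sterol synthesis genes rose (camera adjusted p = 1.84e-14), led by Cyp51, Msmo1, Fdps and Hmgcs1 at log2 fold changes of 3.19, 3.08, 2.79 and 2.78. In the cell cycle list, 31 of 35 members rose, 2 fell and 2 did not pass (adjusted p = 1.84e-14), with the cyclin gene Ccna2 at 2.65, the spindle genes Tpx2 and Aurka at 2.54 and 2.53, and the proliferation marker Mki67 at 2.53. The amino acid stress response list had 17 up and 1 down of 18 (adjusted p = 6.05e-07; adjusted p = 0.167 with an estimated correlation), including Asns, the asparagine synthetase, at 2.46 and the transporter gene Slc7a5 at 2.06. Glycolysis genes were mostly higher, 18 up, 4 down and 4 not past (adjusted p = 0.000751; adjusted p = 0.215 with an estimated correlation), although Pdk1, a pyruvate dehydrogenase kinase gene, had -1.46.

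In the coinhibitory and exhaustion list, 10 of 15 members rose, 4 fell and 1 did not pass (adjusted p = 0.00241), with Nr4a2 at 5.37 ± 0.06, Lag3 at 4.14 ± 0.06, Nr4a3 at 3.14 ± 0.10 and the ligand gene Cd200 at 2.83 ± 0.07. Effector cytokine genes were 7 up and 1 down of the 8 tested among 17 listed (adjusted p = 0.000751). Il10, an anti-inflammatory cytokine, led them at 3.62, followed by the macrophage growth factor Csf1 at 2.99, Il21 at 2.94 and the death ligand Fasl at 1.30. Il10, Csf1 and Il21 were at most 1.86 CPM in Control and reached 10 CPM only in NFAT2 libraries, so they entered the test through their rise. Of the untested members read out below, Tnf and Csf2 fell with NFAT2-CA, Il4 and Ifng rose and Il2 did not pass. The regulatory T cell list had 7 up, 1 down and 2 not past of 10 (adjusted p = 0.00135), led by the costimulatory receptor Tnfrsf9 at 2.83, the chemokine receptor Ccr8 at 2.26, Nrp1 at 2.22 and Tnfrsf4 at 1.98. The follicular helper list had 7 up and 4 down of 11 (adjusted p = 0.0154; adjusted p = 0.0938 with an estimated correlation), with the inhibitory receptor Btla at 1.99 and the transcription factor Maf at -1.98.

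Lower expression marked 3 lists. Of 21 naive and memory genes, 16 fell, 3 rose and 2 did not pass (adjusted p = 0.000377; adjusted p = 0.176 with an estimated correlation). Ly6c2 and Ly6c1, surface genes that are near-identical copies and uncertain one by one, had log2 fold changes of -4.50 and -2.68, and Igfbp4 had -1.76. Interferon-stimulated genes were 13 down, 4 up and 1 not past (adjusted p = 0.0124; adjusted p = 0.0968 with an estimated correlation), with Xaf1 at -2.05, Ifit2 at -1.76, Irf7 at -1.37 and Irgm1 at -1.35. Adhesion and migration genes were 15 down, 4 up and 2 not past (adjusted p = 0.00424; adjusted p = 0.0787 with an estimated correlation), with the chemokine receptor Cxcr3 at -3.22. The sterol synthesis, cell cycle, coinhibitory, effector cytokine and regulatory T cell lists also passed with an estimated correlation, each at an adjusted p of 0.0498.

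Lists that did not stand apart from the other genes still held changed members. The AP-1, IRF and related factors list had 11 up, 6 down and 3 not past of 20 (adjusted p = 0.0554, but 0.0379 without Control replicate 1), with the stress factor Atf3 at 3.17, Irf4 at 2.62 and the AP-1 subunit Fosl2 at 2.20. The NFAT and calcineurin list had 5 up, 9 down and 5 not past of 19 (adjusted p = 0.439), with the calcium channel gene Orai2 at -1.57 and Nfatc2 at -1.23. The counts were 9 up and 7 down of 18 for anergy (adjusted p = 0.338), 5 and 7 of 14 for Th1 and cytotoxic genes (adjusted p = 0.268), and 5 and 3 of 8 for Th2 genes (adjusted p = 0.258). They were 2 and 2 of 4 for Th17 genes (adjusted p = 0.327), where Ahr, the aryl hydrocarbon receptor, rose by 4.81, and 11 and 18 of 34 for T cell receptor signalling (adjusted p = 0.244). Apoptosis genes were 9 up and 12 down of 25 (adjusted p = 0.675), with a median of -0.03 and a mean of 0.17. The 3 tested myeloid genes had a median of 0.15 and a mean of -0.57 (adjusted p = 0.946). Adjusted over the list alone, the counts up and down differed in 3 lists: 5 and 8 for Th1, 12 and 6 for AP-1 and 10 and 12 for apoptosis. The fry test, which asks whether a list moves one way without comparing it with other genes, passed for all 20 lists.

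The second comparison asks what NFAT2 does when its cooperation with AP-1 is impaired. NFAT2-CARIT raised Lag3 19.5-fold, from 60.8 ± 5.18 to 1189 ± 42.6 CPM (n = 3 per group). Bend4, which encodes a BEN domain protein, rose from 3.29 ± 0.452 to 398 ± 6.79 CPM. Cyp51 rose 10.5-fold to 433 ± 1.76 CPM. Cxcr3, the chemokine receptor of Th1 cells, fell from 146 ± 1.43 to 4.69 ± 0.428 CPM.

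Counts were close to those with NFAT2-CA: 6964 of 9233 genes (75.4%) differed from Control, 2962 up and 4002 down. TMM factors gave 3415 up and 3531 down, so this excess of falls also depends on the scaling. The authors' deposited table calls 4216 of 16500 genes and keeps 3733 of the 6964 limma calls. With limma, changes of at least 2-fold were found for 1508 genes, 773 up and 735 down, and the median called change was 0.54 on the log2 scale. Libraries did not overlap for 7104 genes (76.9%, against 10% by chance).

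Bend4 had the largest rise among genes of at least 50 CPM, 6.54 ± 0.07 on the log2 scale (adjusted p = 4.7e-19). Nos2 rose by 6.20 ± 0.08 (adjusted p = 2.5e-18), to 81.0 ± 0.751 CPM. Hspa1a and Hspa1b rose to 99.1 ± 8.24 and 86.3 ± 6.73 CPM, by 6.08 ± 0.15 and 5.49 ± 0.18, and Hdc rose to 77.4 ± 3.63 CPM. Apod, the apolipoprotein D gene on chromosome 16 (31296192 to 31314808), was listed at 0 in all 3 Control libraries and at 59.4 ± 0.878 CPM with NFAT2-CARIT. The largest falls among genes of at least 50 CPM in the higher group were in Cxcr3 at -4.69 ± 0.10 (adjusted p = 8.5e-16), Ifi206 at -4.35 ± 0.14, Ms4a4b at -4.19 ± 0.16, Ifi203 at -3.99 ± 0.16, Tgtp1 at -3.65 ± 0.09 and Cd226 at -3.58 ± 0.10.

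NFAT2-CARIT moved 8 lists apart from the other genes, 5 up and 3 down, each of which NFAT2-CA also moved. Mixed splits of the NFAT2-CARIT and Control libraries, which also keep part of the group difference, still set 2 to 6 lists apart, with 0 genes called. Cell cycle genes were 32 up, 1 down and 2 not past (adjusted p = 5.62e-16; adjusted p = 0.0586 with an estimated correlation), with Aurka at 2.81, Tpx2 and Ccna2 at 2.80 and the mitotic checkpoint gene Bub1 at 2.75. Sterol synthesis genes were 22 up, 0 down and 1 not past (adjusted p = 1.80e-13; 0.0437 with an estimated correlation), with Cyp51 at 3.36, Msmo1 at 3.00, Fdps at 2.85 and Hmgcs1 at 2.74. The coinhibitory list had 12 up, 2 down and 1 not past (adjusted p = 0.000104; 0.0437 with an estimated correlation), led by Lag3 at 4.27 and the 3 Nr4a genes: Nr4a2 at 3.89, Nr4a3 at 3.71 and Nr4a1 at 2.85. Regulatory T cell genes were 7 up, 2 down and 1 not past (adjusted p = 0.00853; adjusted p = 0.0991 with an estimated correlation), with Tnfrsf9 at 2.75, the zinc finger factor Ikzf2 at 2.12, Ccr8 at 1.79 and Tnfrsf4 at 1.76. The amino acid stress list had 15 up, 2 down and 1 not past (adjusted p = 2.51e-05; adjusted p = 0.229 with an estimated correlation), with Asns at 2.75, Slc7a5 at 2.33, its partner chain Slc3a2 at 2.11 and the serine synthesis gene Psat1 at 2.10.

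Naive and memory genes were 16 down, 4 up and 1 not past with NFAT2-CARIT (adjusted p = 0.00221; adjusted p = 0.229 with an estimated correlation), with Ly6c2 at -4.36, Ly6c1 at -3.22, Igfbp4 at -2.04 and Dapl1 at -1.76. Interferon-stimulated genes were 12 down, 5 up and 1 not past (adjusted p = 0.0457; adjusted p = 0.206 with an estimated correlation). Xaf1, Ifit2 and Oas3 had -2.24, -2.11 and -1.70, while the antiviral gene Rsad2 rose by 1.94. Adhesion and migration genes were 14 down, 5 up and 2 not past (adjusted p = 0.0457; adjusted p = 0.206 with an estimated correlation), including Cxcr3. These last calls are marginal: the interferon list stood at 0.0518 without NFAT2-CA replicate 2 and 0.0537 without NFAT2-CA replicate 3, and the adhesion list at 0.0538, 0.0537 and 0.0536 without NFAT2-CA replicate 2, NFAT2-CA replicate 3 or NFAT2-CARIT replicate 1.

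Effector cytokines, glycolysis and follicular helper genes, which NFAT2-CA moved at a correlation of 0.01, did not pass with NFAT2-CARIT. They were 5 up and 2 down of 8 (adjusted p = 0.141), 12 and 8 of 26 (adjusted p = 0.165) and 6 and 4 of 11 (adjusted p = 0.10). Glycolysis and follicular helper genes did not pass with NFAT2-CA under an estimated correlation either. The follicular helper list also did not differ between the vectors (camera adjusted p = 0.533). The AP-1 list had 10 up, 5 down and 5 not past (adjusted p = 0.0808), with Atf3 at 2.46, Irf4 at 1.99 and Fosl2 at 1.82. NFAT and calcineurin genes were 4 up and 11 down of 19 (adjusted p = 0.165), with Orai2 at -1.52 and Nfatc2 at -1.43. The other counts up and down were 13 and 8 for apoptosis (adjusted p = 0.165), 5 and 8 for Th1 (adjusted p = 0.294), 5 and 3 for Th2 (adjusted p = 0.242), 2 and 1 for Th17 (adjusted p = 0.142) and 9 and 20 for T cell receptor signalling (adjusted p = 0.220). Anergy genes were 8 up and 8 down (adjusted p = 0.358), with a median of -0.07 and a mean of 0.40. The myeloid genes had a median of 0.17 and a mean of -0.55 (adjusted p = 0.937). Adjusted over the list alone, the counts up and down became 23 and 0 for sterol synthesis, 10 and 20 for T cell receptor signalling and 5 and 15 for adhesion. The fry test again passed for all 20 lists.

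**Figure D2:**
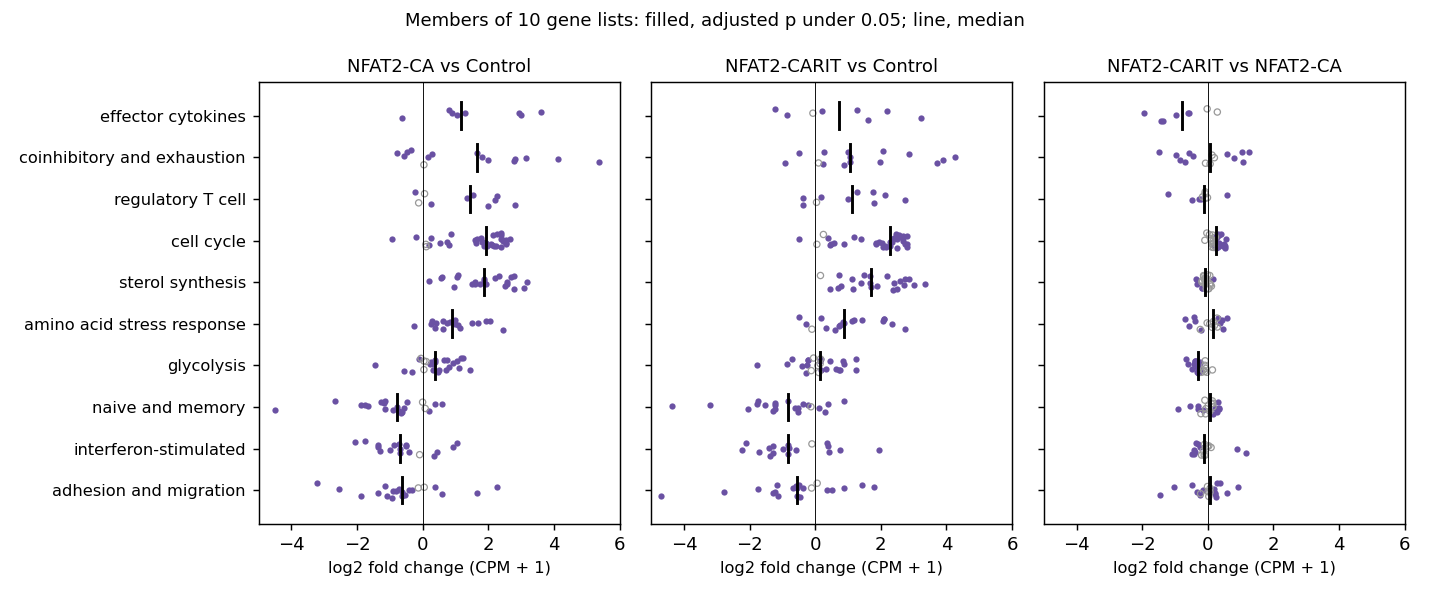
Log2 fold changes (CPM + 1) of the tested members of 10 gene lists in the 3 comparisons. Each point is a gene, filled where its adjusted p is under 0.05, and the vertical bar is the list's median. The cell cycle median is 1.93 with NFAT2-CA and 2.28 with NFAT2-CARIT against Control, and 0.26 between the vectors.

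The vectors changed largely the same genes in the same direction. Of the 6650 genes changed by NFAT2-CA, 5776 (86.9%) changed the same way with NFAT2-CARIT. There were 2452 genes up with both (935 from independent lists) and 3324 down with both (1619 from independent lists). Among the 1230 genes that NFAT2-CA changed at least 2-fold, 1210 changed the same way with NFAT2-CARIT, with a median ratio of log2 fold changes of 1.06. Across genes, which are not independent replicates, the correlation of the log2 fold changes was 0.935, and 88.2% had the same sign. Unchanged groups simulated 50 times against shared controls gave 0.498, 66.5% and 0 genes called the same way. The covariance was 0.640, against 0.0037 in the simulation, a difference of 0.636. Noise of the shared Control libraries is already in the simulation, and its covariance of 0.0037 argues against it as the main source of the overlap. A trait common to all 3 Control libraries would enter both comparisons and cannot be told apart from the vectors. Separate controls were not used, since 3 libraries cannot be split into parts that each keep at least 2.

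**Figure D3:**
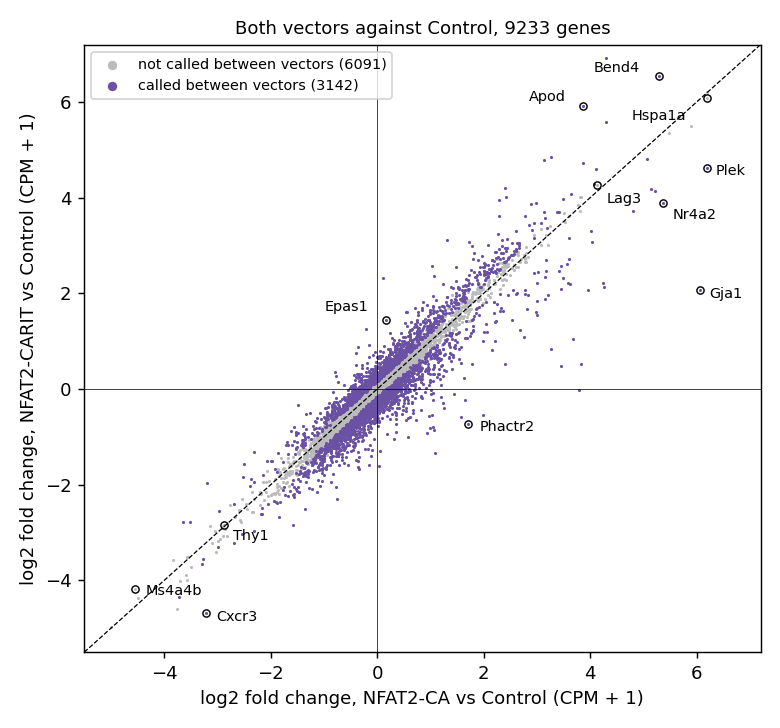
Log2 fold change (CPM + 1) of each of 9233 genes with NFAT2-CA (horizontal axis) and NFAT2-CARIT (vertical axis) against Control, with the 3142 genes that differ between the vectors in purple and the line of equal change dashed. Apod is listed at 0 in Control, so its position depends on the added 1 CPM. Most points lie along the line, and Gja1, Plek and Phactr2 lie below it.

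The third comparison asks which transcripts differ between the 2 vectors, of which NFAT2-CARIT carries the changes that impair cooperation with AP-1. Gja1 differed most, at 93.3 ± 8.20 CPM with NFAT2-CA and 4.94 ± 1.30 CPM with NFAT2-CARIT (n = 3 per group). Il10 was lower with NFAT2-CARIT, at 11.2 ± 0.637 against 31.9 ± 2.86 CPM, and so was Nr4a2, at 77.9 ± 3.23 against 219 ± 8.03 CPM. Ctla4, the coinhibitory receptor gene, was higher, at 407 ± 13.5 against 235 ± 17.4 CPM. With NFAT2-CARIT, 18 of 26 glycolysis genes were lower and 22 of 35 cell cycle genes slightly higher, but neither list passed with an estimated correlation (adjusted p = 0.209 for each).

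Between the vectors, 3142 of 9233 genes (34.0%) differed, 1394 higher and 1748 lower with NFAT2-CARIT. The excess of lower genes is not stable: TMM factors gave 1607 higher and 1586 lower, quantile normalization 1535 and 1461, and a filter of 50 CPM 891 and 757. Of the 3142 genes, 116 differed at least 2-fold, 29 higher and 87 lower, and the median called difference was 0.32 on the log2 scale. Libraries did not overlap for 4526 genes (49.0%, against 10% by chance). The number called depends on the method, since the authors' deposited table calls 468 genes, and 41 limma calls among the 100 gene values read out for this comparison do not pass there.

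Of the 6650 genes that NFAT2-CA changed, 2497 differed between the vectors. NFAT2-CARIT had the weaker or opposite effect on 1085 of them (1116 from independent lists): 569 changed less in the same direction, 395 did not pass against Control and 121 changed the opposite way. It had the stronger effect on the other 1412. Among all genes changed by NFAT2-CARIT, 2086 differed from NFAT2-CA in the direction of their own change (1205 from independent lists): these 1412, 553 not called with NFAT2-CA, and the same 121 that changed the opposite way. For 3795 genes changed the same way by both, no difference between the vectors was called. The simulated unchanged groups gave 0 genes of either kind.

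Gja1 had the largest fall from NFAT2-CA to NFAT2-CARIT, -4.01 ± 0.14 on the log2 scale (adjusted p = 1.9e-11). Ddr1, a collagen receptor kinase, had -1.87 ± 0.08 (adjusted p = 6.3e-11), at 39.2 ± 2.87 against 146 ± 6.00 CPM. Plek had -1.56 ± 0.06 (adjusted p = 6.6e-11), at 72.5 ± 1.31 against 216 ± 8.42 CPM. Phactr2, an actin and phosphatase regulator, had -2.44 ± 0.09 (adjusted p = 3.6e-11) and stood at 12.1 ± 1.43 CPM, below its Control level of 20.8 ± 2.39 CPM. Gnptab, a lysosomal enzyme targeting gene, and Ppp2r3a, a phosphatase subunit gene, had -1.64 ± 0.08 and -1.58 ± 0.06, and both were also below Control with NFAT2-CARIT.

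Higher with NFAT2-CARIT were Apod at 2.05 ± 0.09 (adjusted p = 1.7e-10), from 13.6 ± 0.429 to 59.4 ± 0.878 CPM, and Ramp3, a receptor chaperone, at 1.65 ± 0.09 (adjusted p = 2.4e-09), from 109.5 ± 12.8 to 346 ± 37.7 CPM. The membrane protein gene Emp1 had 1.33 ± 0.08 and the triglyceride synthesis gene Dgat1 had 1.30 ± 0.06. Epas1, which encodes the hypoxia factor HIF-2 alpha, had 1.27 ± 0.06 (adjusted p = 2.8e-10), at 152 ± 5.23 CPM against 62.3 ± 0.869 with NFAT2-CA and 55.5 ± 3.37 in Control.

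Differences between the vectors set 5 lists apart, none of which passed with an estimated correlation. Mixed splits of the NFAT2-CARIT and NFAT2-CA libraries, which keep part of the difference between the vectors, set 0 to 2 lists apart, with 0 genes called. Effector cytokine genes were 0 up, 6 down and 2 not past (adjusted p = 0.000180; adjusted p = 0.0971 with an estimated correlation), with the TNF family ligand Tnfsf14 at -1.93, Il10 at -1.43, Csf1 at -1.38 and Tnfsf8 at -0.97. Tnfsf14 and Csf1 reached 10 CPM only in NFAT2-CA libraries, so they entered the test through their higher level there. Only 8 of the 17 listed members were tested. Glycolysis genes were 0 up, 18 down and 8 not past (adjusted p = 6.60e-07; adjusted p = 0.209 with an estimated correlation), with the oxygen sensor Egln3 at -0.65, the hexokinase Hk2 at -0.59, Bnip3 at -0.47 and Pfkm at -0.43. Th2 genes were 1 up, 6 down and 1 not past (adjusted p = 0.0295; adjusted p = 0.368 with an estimated correlation; 0.0589 without NFAT2-CARIT replicate 3), among them the lineage factor Gata3 at -0.43. Cell cycle genes were 22 up, 0 down and 13 not past (adjusted p = 4.24e-08; adjusted p = 0.209 with an estimated correlation), with the replication gene Mcm5 at 0.54 and Rrm2, a ribonucleotide reductase subunit, at 0.53. Apoptosis genes were 11 up, 3 down and 11 not past (adjusted p = 0.0170; adjusted p = 0.209 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 0.60 and the caspase regulator Birc2 at 0.56. Mcm5 and Rrm2 do not pass in the authors' deposited table (adjusted p = 0.14 and 0.63).

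The coinhibitory list did not stand apart from the other genes between the vectors, with 5 up, 6 down and 4 not past (adjusted p = 0.944). Nr4a2 had -1.48 ± 0.06, whereas Nr4a1, the related immediate early gene, had 1.03 ± 0.09 and Cd274, which encodes PD-L1, had 1.24 ± 0.07. AP-1 and related factors were 5 up and 7 down of 20 (adjusted p = 0.533), with Irf4 at -0.63 ± 0.07, and NFAT and calcineurin genes were 1 up and 5 down of 19 (adjusted p = 0.533). Sterol synthesis genes were 1 up, 4 down and 18 not past (adjusted p = 0.533). The remaining counts up and down were 5 and 5 for amino acid stress (adjusted p = 0.533), 2 and 7 for interferon-stimulated (adjusted p = 0.192), 1 and 4 for regulatory T cell (adjusted p = 0.192), 3 and 6 for follicular helper (adjusted p = 0.533) and 4 and 5 for Th1 genes (adjusted p = 0.80). They were 2 and 1 for Th17 (adjusted p = 0.533), 8 and 10 for T cell receptor signalling (adjusted p = 0.854), 3 and 6 for anergy (adjusted p = 0.944) and 1 and 1 for myeloid genes (adjusted p = 0.944). Medians and means differed in sign for naive and memory genes (6 up, 5 down; 0.06 and -0.02; adjusted p = 0.80) and for adhesion genes (9 up, 6 down; 0.07 and -0.03; adjusted p = 0.533). Adjusted over the list alone, the counts up and down became 1 and 6 for effector cytokines, 6 and 6 for coinhibitory, 4 and 6 for anergy, 4 and 6 for follicular helper, 23 and 0 for cell cycle, 1 and 3 for sterol synthesis, 7 and 5 for amino acid stress and 12 and 3 for apoptosis genes. The fry test passed for 13 lists.

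A fixed set of T cell genes was read out whatever its result. Lag3 rose with both vectors and did not differ between them at the threshold (log2 fold change 0.13 ± 0.06, adjusted p = 0.13, but 0.032 without Control replicate 3, 0.048 with only the 6 libraries compared and 0.02 with array quality weights). Tigit, another coinhibitory receptor gene, rose from 16.6 ± 2.01 to 119 ± 1.71 CPM with NFAT2-CA and 73.0 ± 3.61 CPM with NFAT2-CARIT (difference -0.70 ± 0.08, adjusted p = 4.2e-06). Ctla4 rose by 0.28 ± 0.07 (adjusted p = 0.0033; 0.057 in the authors' deposited table) and 1.07 ± 0.07 (adjusted p = 1.5e-09). Tox, a factor of exhausted T cells, rose by 1.65 ± 0.08 and 1.07 ± 0.08, with a difference of -0.58 ± 0.08 (adjusted p = 4.9e-05; 0.29 in the authors' deposited table). Tcf7, the factor of naive and memory cells, had -0.73 ± 0.05 and -0.52 ± 0.05, from 1524 ± 56.7 CPM to 919.8 ± 9.15 and 1062 ± 12.2 CPM. Rcan1, a calcineurin inhibitor that NFAT induces, stood at 10.1 ± 1.01, 16.6 ± 1.63 and 6.85 ± 0.372 CPM in Control, NFAT2-CA and NFAT2-CARIT. It rose by 0.67 ± 0.10 (adjusted p = 2.3e-05) with NFAT2-CA and had -0.50 ± 0.10 (adjusted p = 0.00038) with NFAT2-CARIT. Neither passes in the authors' deposited table (adjusted p = 0.20 and 0.34), while their difference of -1.16 ± 0.10 (adjusted p = 3.8e-07) passes in both.

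The other genes of this set were below 10 CPM in too many libraries and were read from a fit without that filter. Il2, the T cell growth factor, was below 1 CPM in each group, with log2 fold changes of -0.16 ± 0.15 (adjusted p = 0.41) and -0.10 ± 0.15 (adjusted p = 0.61), and Egr2, a factor of anergic cells, had -0.18 ± 0.16 (adjusted p = 0.34) and -0.25 ± 0.16 (adjusted p = 0.18, but 0.048 with array quality weights). Ifng, the Th1 cytokine, was also below 1 CPM. Its rise of 0.50 ± 0.18 with NFAT2-CA (adjusted p = 0.029) did not pass without Control replicate 2 (adjusted p = 0.10), Control replicate 3 (0.085) or NFAT2-CA replicate 2 (0.10), or with quantile normalization (0.12), and with NFAT2-CARIT it was 0.21 ± 0.18 (adjusted p = 0.34). Havcr2, which encodes the coinhibitory receptor TIM-3, rose from 0.679 ± 0.325 to 2.95 ± 0.583 CPM with NFAT2-CA (adjusted p = 7.3e-06) and 6.64 ± 0.318 CPM with NFAT2-CARIT (adjusted p = 8.6e-09), a difference of 0.96 ± 0.16 (adjusted p = 0.00052; 0.94 in the authors' deposited table). Pdcd1, which encodes PD-1, rose by 0.77 ± 0.14 (adjusted p = 0.00022) and 0.43 ± 0.14 (adjusted p = 0.015). The second value was 0.24 (adjusted p = 0.090) without Control replicate 1 and 0.41 (adjusted p = 0.053) without NFAT2-CARIT replicate 2. Their difference, -0.34 ± 0.14 (adjusted p = 0.11), passed without Control replicate 1 (0.028), with only the 6 libraries compared (0.028) and with array quality weights (0.042).

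Il4, the Th2 cytokine, rose by 0.63 ± 0.14 (adjusted p = 0.0011) and 0.74 ± 0.14 (adjusted p = 0.00027), and the inflammatory cytokine Tnf had -0.54 ± 0.13 (adjusted p = 0.0020) and -0.53 ± 0.13 (adjusted p = 0.0021). Csf2, the GM-CSF gene, had -0.56 ± 0.15 with NFAT2-CA (adjusted p = 0.0039) and -0.06 ± 0.15 with NFAT2-CARIT (adjusted p = 0.75). Their difference for Csf2, 0.50 ± 0.15 (adjusted p = 0.022), did not pass without NFAT2-CA replicate 1 (0.071) or 2 (0.055) or NFAT2-CARIT replicate 1 (0.093) or 3 (0.057). Foxp3, the regulatory T cell factor, had 0.25 ± 0.12 with NFAT2-CA (adjusted p = 0.099, but 0.049 with TMM factors and 0.013 with array quality weights) and -0.45 ± 0.12 with NFAT2-CARIT (adjusted p = 0.0047). The difference for Foxp3 was -0.71 ± 0.12 (adjusted p = 0.00069; 0.97 in the authors' deposited table). None of the calls of Ifng, Pdcd1, Il4, Tnf and Csf2 passes in the authors' deposited table, nor does that of Foxp3 with NFAT2-CARIT (adjusted p = 0.55).

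Marker genes of other cell types were summed for each group. The B cell list summed to 419.9 ± 6.00 CPM in Control, 209.9 ± 2.80 with NFAT2-CA and 194 ± 11.7 with NFAT2-CARIT, nearly all of it Ighm, the IgM heavy chain (415, 208 and 191 CPM), while Cd79b, a B cell receptor subunit gene, was at 2.37 CPM or less. CD8 markers summed to 12.9 ± 0.70, 29.4 ± 1.30 and 23.1 ± 0.80 CPM, mostly Cd8b1 (12.7, 28.9 and 21.4 CPM). Myeloid and dendritic markers summed to 146 ± 10.8, 158 ± 9.50 and 144 ± 6.00 CPM, a flat sum over members that moved apart. The Fc receptor gene Fcgr3 stood at 28.0, 4.61 and 6.16 CPM and the integrin gene Itgam at 7.98, 0.701 and 1.34 CPM, while the MHC class II genes H2-Ab1 and H2-Eb1 stood at 63.5, 91.5 and 71.6 CPM and at 4.14, 10.6 and 7.77 CPM. Cst3, the cystatin C gene, was at 34.8, 38.7 and 40.3 CPM. NK markers stayed between 4.0 and 4.4 CPM and erythroid and platelet markers between 2.8 and 3.0 CPM in the group means. The 1 listed histone gene, H1f0, stood at 155, 134 and 101 CPM, and no gene of the mitochondrial chromosome is listed. The chemokine list had 1 tested member, Ccl5, with log2 fold changes of -0.63 with NFAT2-CA (called down by limma, but adjusted p = 0.23 in the authors' deposited table) and 0.09 with NFAT2-CARIT (not past).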

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

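The tests of a lower dose and of sequencing depth were chosen only after the difference between the vectors was seen, and the 1 CPM filter behind the low-expressed genes was added after the data were seen.

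A set of 121 genes stood out because the vectors moved them in opposite directions against Control and limma also called the difference between the vectors. Of these, 81 rose with NFAT2-CA and fell with NFAT2-CARIT, and 40 did the reverse. The largest differences among those of at least 50 CPM in the higher group were in Phactr2 (-2.44 on the log2 scale), Gnptab (-1.64), Ppp2r3a (-1.58), the prostaglandin receptor gene Ptger2 (-1.37), Qser1 (-1.27) and the stress response gene Fam129a (-1.26). Ptger2 stood at 25.7, 60.5 and 22.7 CPM in Control, NFAT2-CA and NFAT2-CARIT, and Fam129a at 49.7, 89.1 and 36.7 CPM. The falls against Control with NFAT2-CARIT were small for Ptger2 (-0.16 ± 0.07, limma adjusted p = 0.042) and Qser1 (-0.22 ± 0.09, adjusted p = 0.029).

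The difference between NFAT2-CARIT and NFAT2-CA may be technical, a matter of dose, or the loss of AP-1 cooperation. Nfatc1 itself was lower with NFAT2-CARIT, although its values cannot be read as the amount of vector. A weaker dose of the same activity would leave few genes with a larger change. Of the NFAT2-CA genes that differ, 56.5% changed more with NFAT2-CARIT, which argues against a weaker dose as the whole cause. A stronger dose with NFAT2-CARIT was not tested. Depth was higher in NFAT2-CARIT replicates 1 and 2, and 2581 and 2367 genes were still called when either was left out. The other deeper library stayed in each time, so these counts cannot exclude a part of depth. The share called was 34.0% among genes of at least 50 CPM and 34.1% among those of 10 to 50 CPM. The loss of AP-1 cooperation, which the design names, stays open and was not tested, as does a dose effect on part of the genes.

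Genes of 1 to 10 CPM lay outside the comparisons of the report, and many of them also differed. With a filter of 1 CPM, limma called 2012 of 3863 such genes with NFAT2-CA (917 up, 1095 down), 2281 with NFAT2-CARIT (882 up, 1399 down) and 737 between the vectors (218 up, 519 down).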

How the results depend on the processing

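The filter of 1 CPM was chosen after the data were seen; the test of what sets the noise in the authors' deposited table was planned. Whole reads could not be recovered, so the planned edgeR and DESeq2 fits on reads were not run. Counts of called genes stayed within 1.5 times with pseudocounts of 0.5 and 5, no filter (9005, 9693 and 3580 genes for NFAT2-CA, NFAT2-CARIT and their difference), a filter of 1 CPM (8577, 9202 and 3743), TMM factors (6575, 6946 and 3193), quantile normalization (6645, 6911 and 2996) and only the 6 libraries compared (6507, 6929 and 3369).

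A filter of 50 CPM tested 4616 genes and so called fewer: 3417, 3554 and 1648, with 3004 changed the same way, 610 weaker or opposite and 1060 stronger or opposite with NFAT2-CARIT (oppositely changed genes enter both counts). With array quality weights 4821 genes differed between the vectors and 1791 were weaker or opposite; the cause was not tested. With an estimated correlation 5, 2 and 0 lists passed instead of 11, 8 and 5. The estimate was above the set 0.01 for some lists, such as cell cycle (0.165) and amino acid stress (0.373). It was below 0.01 for others, such as effector cytokines (-0.086). Between the vectors, the camera p of effector cytokines still rose from 2.7e-05 to 0.00485 with that estimate. Regulatory T cell genes with NFAT2-CARIT (-0.085) went from 0.00256 to 0.0198. These values argue against a higher correlation among members as the cause for these lists. How much of the loss of other lists the estimates explain was not tested.

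The authors' deposited table calls 3602, 4216 and 468 genes, with 3062 changed the same way, 205 weaker or opposite and 239 stronger or opposite; for Nfatc1 with NFAT2-CARIT against Control it gives 0.21 (adjusted p = 0.19). Among named genes 14, 9 and 41 calls of the 3 comparisons do not pass there, and none changes direction. A candidate explanation is that CPM values entered the table's test as if they were reads. It was checked for NFAT2-CARIT against NFAT2-CA only, not for the comparisons with Control. Among 2818 genes of 10 to 30 CPM the SE implied by its p-values was 1.09 times the Poisson error of such counts (medians 0.313 and 0.286), against a limma SE of 0.0933. The ratio was higher among more expressed genes, up to 1.57 among 489 genes of 300 to 1000 CPM. More genes in the adjustment cannot account for it, since adjusting its p-values over the genes tested here gave 526 calls between the vectors.

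Leaving out each library in turn gave 6200 to 6659, 6568 to 7043 and 2367 to 3606 called genes, 5463 to 5766 changed the same way, 830 to 1253 weaker or opposite, 1556 to 2314 stronger or opposite, and 11 to 12, 6 to 8 and 4 to 5 lists. Nfatc1 with NFAT2-CARIT against Control ranged from 0.12 to 0.26 and did not pass without Control replicate 3 or NFAT2-CARIT replicate 3.

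Of 318 named gene values, 246 kept their direction and side of the threshold under each alternative that gave them a value. Directions reversed in 4, none of them called: Egr2 between the vectors (0.02 with quantile normalization; -0.16 to 0.04 over libraries left out), Il2 (-0.04 with array quality weights; -0.07 to 0.17) and Tnf (-0.07; -0.04 to 0.11) between the vectors, and Csf2 with NFAT2-CARIT against Control (-0.19 to 0.02). The cause was not tested.

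The replicate numbers gave no clear sign of paired libraries, though 3 libraries per group cannot settle it. The deviations of same-numbered libraries correlated between -0.24 and 0.31, over 0.1 in 2 of 9 pairs. Those of differently numbered libraries correlated between -0.38 and 0.39, over 0.1 in 7 of 18 pairs. Not every library correlated best with its own number. With the replicate number as a block 6527, 6900 and 2919 genes and 11, 6 and 5 lists were called; the interferon and adhesion lists with NFAT2-CARIT stood at an adjusted p of 0.056. Depth limits the genes below 1 CPM, which rest on 20 to 38 reads or fewer per library.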

Other observations

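The tests of a heat-shock response and of handling were chosen only after the rise of Hspa1a and Hspa1b was seen. The splits that keep the Control libraries together were run apart after the drawn ones were seen. The counts of drawn splits and of splits within each gene comparison were planned.

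Hspa1a and Hspa1b rose with both vectors, and 6 of 6 NFAT2 libraries lay above each Control library for both genes (Hspa1a at least 89.6 CPM against at most 0.951 CPM). A heat-shock response may be considered. Of 15 other chaperones and cochaperones 6 rose with both vectors, among them Hspa4l (50.3, 349 and 621 CPM in Control, NFAT2-CA and NFAT2-CARIT), Hsph1 (28.3, 61.2 and 78.6), Dnajb1 (76.7, 155 and 187) and Hsp90aa1 (77.6, 136 and 177). With both vectors 5 (33.3%) fell, among them Ahsa1 (66.9, 38.1 and 34.5 CPM) and, by less, Bag3, Chordc1 and Cacybp, which argues against it as the whole cause of the chaperone changes, while a part in the rises stays open. The falls of Bag3 and Cacybp with both vectors and that of Chordc1 with NFAT2-CA pass in limma but not in the authors' deposited table. Handling that differed between Control and NFAT2 cultures cannot be told apart from the vectors, since it would follow the same groups. An effect of NFAT2 on the pair stays open and was not tested.

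Each gene comparison sets 3 libraries against 3, which allows 10 splits, too few for a share under 0.05. The real split was the 1 with the most called genes each time: 6650, 6964 and 3142, with 0 called by limma in the highest other split. For gene lists the real split gave 11, 8 and 5. The other splits, with 0 genes called, still gave 3 to 7, 2 to 6 and 0 to 2. Camera at its set inter-gene correlation can therefore call lists where limma calls no gene. Each other split mixes the groups unevenly, 2 libraries of a group with 1 of the other, and so keeps part of their difference. The mixing also widens the spread within the groups, which leaves fewer genes to be called. How many of the 11, 8 and 5 lists would be called without a group difference was not tested. For the comparison across the vectors, 100 splits of the 9 libraries were drawn. A count as large as the real 5776 genes changed the same way came in 1 of 100 splits, the real one included. The highest other was 5384, in a split that kept the Control libraries together and mixed the rest. For the 1085 weaker or opposite genes the share was 4 of 100 (highest other 5384). It was 1 of 100 for the 2086 stronger or opposite genes (highest other 79). Each share is under 0.05, but most drawn splits broke up the Control libraries. Chance in how the NFAT2 libraries were grouped is therefore not excluded. With Control kept together under its own name, the 19 other splits gave 5327 to 5776 genes changed the same way. They gave 0 to 2086 weaker or opposite and 0 to 1085 stronger or opposite genes. The highest counts, 5776, 2086 and 1085, are those of the real groups with the vector names exchanged. Splits that mixed the libraries of the vectors called 0 genes between them, and so gave 0 weaker and 0 stronger genes. These mixed splits are too few for a share under 0.05. The 3 larger drawn splits for the 1085 genes kept the Control libraries together under the name of NFAT2-CA. No drawn split put them together under the name of NFAT2-CARIT, so the value of 79 depends on the draw: the 20 such splits, run apart, gave 5327 to 5776 stronger or opposite genes. Such counts point to the separation of Control from the other libraries.

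Thy1, which encodes a T cell surface protein, was chosen after its values were seen. It stood at 4748 ± 235 CPM in Control, 649 ± 14.8 CPM with NFAT2-CA and 657 ± 7.40 CPM with NFAT2-CARIT (mean ± SD, 3 libraries each; log2 fold changes -2.87 ± 0.06 and -2.85 ± 0.06, limma adjusted p = 3.4e-16 and 3.2e-16). Actb, the beta-actin gene often used as a reference, stood at 2902 ± 86.0, 1348 ± 35.4 and 1435 ± 45.9 CPM. In NFAT2-CA replicate 3 the nuclear RNA Malat1 was at 6225 CPM against 1864 and 1722 CPM in replicates 1 and 2, and Neat1 at 659 CPM against 177 and 201 CPM. Malat1 was at 1468 to 1820 CPM in the Control libraries and 2272 to 3223 CPM with NFAT2-CARIT. Neat1 was at 49.0 to 72.8 CPM in the Control libraries and 200 to 261 CPM with NFAT2-CARIT.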
